A study of Sus scrofa with 2 samples.

How the data were processed

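Single-cell RNA sequencing libraries of cultured porcine adipose-derived stem cells (ADSCs) were analysed. The labels give 1 group of 2 libraries, numbered 1 and 2 in their titles, made with the Chromium Single Cell 3' chemistry (v3.1) from polyadenylated RNA. In this chemistry each captured molecule carries a unique molecular identifier (UMI) and each droplet a barcode, so that amplified copies of a molecule are counted once. The labels do not say whether the libraries came from separate animals or cultures. The main tests remove the mean difference between the libraries. Their p-values therefore measure only how far differences between groups of cells disagree between these libraries, which may be technical.

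The deposited files hold, for each library, whole-number UMI counts per gene and barcode, without normalization. The counts were made with Cell Ranger 7.0.0 per the file headers, and with Cell Ranger 7.00 and the genome build Sscrofa11.1 per the submitters' processing notes. The gene annotation and the setting that separated cells from empty droplets are not given in the sources used here. The lowest UMI count of any barcode in the deposited files was 500. The files name 28155 genes by symbol, and each identifier is the symbol with a prefix. Of 407 genes in the 19 functional lists 393 were found by symbol, 3 of them under an older symbol (CYR61 for CCN1, CTGF for CCN2 and CYP51 for CYP51A1). The files hold 23 mitochondrial genes, all of ribosomal or transfer RNA, so the mitochondrial share given here does not count mitochondrial messenger RNA and is lower than in the usual definition.

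Library 1 held 12251 barcodes and 211527905 UMIs, and library 2 held 12956 barcodes and 246316928 UMIs. Barcodes with at least 1000 genes and at most 15% of UMIs from mitochondrial genes were kept as cells, which left 10559 (86.2%) and 11984 (92.5%). All 1692 and 972 barcodes left out held fewer than 1000 genes, and 17 and 100 of them also exceeded the mitochondrial limit. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.08. It marked 3 cells in each library (0.0284% and 0.0250%), below the 0.5% under which the caller was taken not to have worked, so no doublets were removed. As an alternative chosen after seeing the data, the 8% of cells with the highest doublet scores were left out (845 and 959 cells).

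Cells were clustered on 2000 variable genes, ranked within each library, after scaling to 10000 UMIs per cell and a log transform. Each gene was scaled within its library and limited to values of 10 in size. The first 30 principal components, 15 nearest neighbours and the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9, resolution 0.4) followed. All genes of the functional lists and the mitochondrial genes were left out of the clustering, and only genes of those lists are reported as results across clusters. Clusters and tests still rest on the same cells, so list genes that vary with the clustered genes differ partly by construction. Clusters are named by number, and leading genes only identify them. Clusters with at least 50 cells in each library were tested.

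To define classes from UMIs, each cell was thinned at random to 5000 UMIs, and 978 and 386 cells with fewer were left out, which left 9581 and 11598. A cell was called cycling with UMIs of at least 3 of 15 core cycle genes (MKI67, TOP2A, CDK1, CCNB1, CCNA2, BIRC5, UBE2C, CENPF, NUSAP1, TPX2, AURKB, PLK1, HMMR, KIF11 and BUB1) and non-cycling with none. Cells with 1 or 2 were left out. Thinning set the class of a cell, and the tests used its full counts. A cell was called CD74-detected with at least 1 CD74 UMI after thinning, and this comparison was to be run only with at least 50 cells per class and library.

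Cells are not replicates. Counts were summed per library and class or cluster and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, robust fit) in R 4.3.3, with the library as a replicate block since both classes come from the same libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, an absolute log2 fold change of at least 0.5 and the same sign in both libraries. For the cycling comparison the adjustment covered all genes tested, and for clusters, each set against the mean of the other clusters, all genes and clusters. The cycling comparison has 1 residual degree of freedom per gene and edgeR's prior degrees of freedom were infinite, so the spread was pooled over genes and very small p-values rest on that pooling. Gene lists were also tested with fry (limma 3.58.1), which asks whether the genes of a list move one way on balance, and its mixed form whether they move either way. Fry does not set a list against other genes.

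Library 1 and library 2 were compared without a test, since each is a single sample. CPM values (counts scaled to a library total of 1e+06 UMIs) come from the summed deposited counts, with exact Poisson 95% intervals where given, and list medians of log2(CPM + 1) differences were set against 10000 random lists matched on expression in 20 bins. Only genes with a mean of at least 10 CPM over the 2 libraries entered. Shares of cells have exact Clopper-Pearson 95% intervals, and a share of 0 is given with the limit of 3 counts of the total. Intervals and limits cover counting error only. Gene spans (start to end of the annotated gene) were matched by symbol to a RefSeq gene table for Sscrofa11.1, which gave a span for 100% of the 8042 genes compared.

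The gene lists, cell type markers, filters, thresholds and tests were fixed before the data were examined. Genes named per cluster are, among called list genes with a mean of at least 10 CPM, the 3 with the largest rise and the 2 with the largest fall. For the cycling comparison they are the 8 with the largest rise and the 8 with the largest fall among called genes outside the core cycle list with a mean of at least 10 CPM. Genes with placeholder names (such as LOC numbers), mitochondrial genes and transfer RNA genes were left out of that ranking. For each list described, up to 4 called members with the largest absolute change serve as examples. Any other gene was chosen after its values were seen: between the libraries, genes were taken from the ends of the ranking by log2 ratio, without placeholder names and mitochondrial genes, and from the lists.

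The tests were run on simulated counts with 200 changed genes before use. In the cycling simulation (17108 genes tested) 98.5% of genes changed by a log2 of 0.75 and 100% of those changed by 1 or 2 were called, with 5 unchanged genes called, and 0 with no gene changed (17141 tested). In the cluster simulation (17281 genes tested) the shares were 89.6%, 98.5% and 100%, with 3 unchanged genes called, and 0 with no gene changed (17292 tested). All simulated genes shared the same spread, as a pooled fit assumes, so these numbers of false calls need not hold in the real data.

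Alternatives covered DESeq2's size factors in edgeR, the DESeq2 1.42.0 Wald test, no low count filter, no replicate block, no minimum fold change or one of 1, each library left out, a mitochondrial limit of 10%, resolutions of 0.2 and 0.8, scaling over both libraries together, list genes kept in the clustering, thinning to 2000 UMIs or none, at least 5 core genes, and at least 2 CD74 UMIs. An alternative without clusters 4 to 6 was added after seeing the data. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.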

Results

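The transcriptomes of ADSCs, the fibroblast-like progenitor cells that grow out of digested fat in culture, were measured cell by cell in Bama miniature pigs. The cells came from adipose tissue of the chest and were expanded for 3 generations in culture before freezing, per the labels. The series title names keloid prevention, keloids being scars that grow beyond the wound, and functional subgroups of ADSCs. The labels give 1 group of 2 libraries and no treatment, so the comparisons are between subgroups of cells inside each library and between the libraries. After filtering, library 1 held 10559 cells with a median of 19845 UMIs and 4454 genes, and library 2 held 11984 cells with a median of 19651.5 UMIs and 4537 genes. Summed over cells these came to 209737159 and 245421850 UMIs.

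Genes of fibroblasts and other stromal cells were abundant in both libraries. COL1A2, which encodes a chain of type I collagen, reached 2075 CPM in library 1 and 3034 CPM in library 2, COL3A1 of type III collagen 981 and 1497 CPM, and DCN, a small matrix proteoglycan, 736 and 716 CPM. THY1 (CD90) was at 378 and 323 CPM and CD44 at 201 and 172 CPM, while NT5E (CD73) was at 6.92 and 7.57 CPM. Of the 10 stromal markers 8 reached 10 CPM in each library, with a median of 458.6 and 415.7 CPM. PDGFRA, a receptor of mesenchymal progenitors, was at 122 and 156 CPM, and PPARG, the nuclear receptor that drives fat cell formation, at 21.98 and 20.32 CPM. ADIPOQ and FABP4, made by mature fat cells, stayed below 1 CPM in both libraries. The secreted factors FGF7 (354 and 470 CPM) and IL33 (332 and 356 CPM) were higher than VEGFA (43.6 and 30.3 CPM) and HGF (4.85 and 7.73 CPM).

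Markers of other cell types were low. The median CPM of the fat cell list was 0.169 and 0.0326 in libraries 1 and 2, of the endothelial list 0.119 and 0.0856, of the macrophage list 0.145 and 0.145, of the lymphocyte list 0.0143 and 0.0102, and of the mural list 1.29 and 0.862. The mesothelial list had medians of 0.0334 and 0.0489 CPM, the epithelial list 0.0381 and 0.0245, the Schwann cell list 0.0572 and 0.0285, the muscle progenitor list 0.0405 and 0.0183, the erythroid list 0.00954 and 0.00611, and the bone and cartilage list 0.174 and 0.0998. Single members were higher: KRT7, a keratin of simple epithelia, reached 76.1 and 71.5 CPM, CD14, a lipopolysaccharide co-receptor, 25.4 and 21.7 CPM, KRT19 15.1 and 12.8 CPM, NCAM1 11.6 and 14.4 CPM, PECAM1 11.43 and 15.01 CPM, and ABCC9 7.31 and 14.2 CPM. These 6 genes were chosen after their values were seen.

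The libraries differed in the level of genes of early stress and inflammation. Immediate early genes, transcribed within minutes of a stimulus, were higher in library 1 by a median log2 of 0.73 over 14 genes, and inflammatory genes by 0.71 over 15 genes. In both lists 6 genes were at least 2-fold higher in library 1 and 0 in library 2, while 2 immediate early genes, EGR1 (77.6 against 113 CPM) and FOSB (79.3 against 101 CPM), were lower in library 1. IER3, an immediate early gene, was at 505 CPM (502-509) in library 1 and 69.9 CPM (68.9-71.0) in library 2. The phosphatase gene DUSP1 was at 933 (929-938) against 273 CPM (271-275), the chemokine gene CXCL2 at 286 (284-288) against 31.7 CPM (31.0-32.4), and the cytokine gene IL6 at 52.3 (51.3-53.3) against 14.7 CPM (14.3-15.2). HSPA5, the main chaperone of the endoplasmic reticulum, was at 914 (910-919) against 280 CPM (278-282), and its list of stress and unfolded protein genes had a median of 0.43. All 3 medians lay above all 10000 random lists of the same size and expression. Matrix remodelling (0.28), cholesterol synthesis (0.20), senescence and p53 (0.18) and interferon response genes (0.16) also lay above the middle 95% of random lists.

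Collagen and matrix genes were lower in library 1, by a median log2 of -0.36 over 17 genes, below all random lists. COL5A2 was at 339 CPM (337-342) in library 1 and 691 CPM (688-694) in library 2, whereas COL12A1 of the same list went the other way, at 271 (269-274) against 122 CPM (121-124). Interstitial progenitor genes (-0.34 over 8 genes) and bone and cartilage genes (-0.47 over 4 genes) lay below the middle 95% of random lists, and the other lists lay inside it. Across genes the ratio between libraries fell with gene span (Spearman -0.42), and the random lists were matched on expression but not on span. That trend was removed only for the immediate early list, so the other list differences, here and above, are not separate from it. Among 8042 genes with a mean of at least 10 CPM, 208 were at least 2-fold higher in library 1 and 21 in library 2. Random splits of library 1 gave 0 such genes. Leaving out placeholder names and mitochondrial genes, ITGAM, an integrin chain of myeloid cells, differed most, at 30.2 (29.4-30.9) against 0.550 CPM (0.461-0.651), and CCDC173 most in the other direction, at 12.0 (11.5-12.5) against 57.2 CPM (56.2-58.1). Pearson's r across genes of log2(CPM + 1) was 0.961, where genes are not independent replicates. The chi-square per degree of freedom was 224.651 between libraries and 1.48 between the splits, and 46 barcodes were shared, so the files do not hold 1 library deposited as 2. With 1 library on each side these differences have no replicate check and no p-value.

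**Figure D1:**
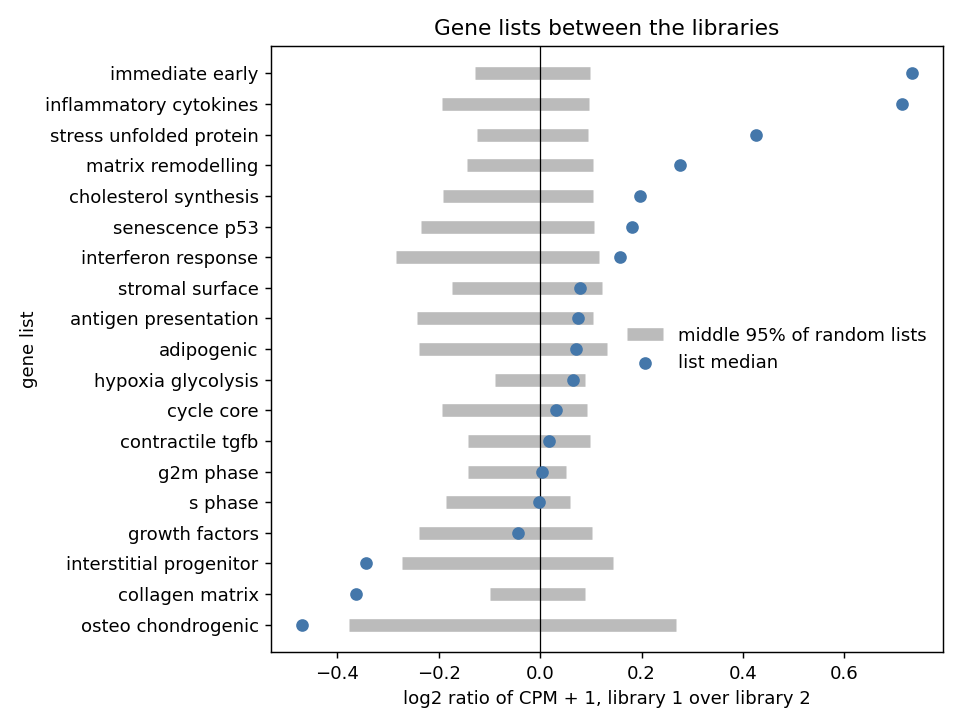
Median log2 ratio of CPM + 1 between library 1 and library 2 for the genes of each list (points), with the middle 95% of 10000 random lists of the same size and expression (grey bars). Immediate early and inflammatory genes lie furthest to the right, at 0.73 and 0.71, and collagen and matrix genes lie at -0.36.

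Many cells were in cycle. After thinning to 5000 UMIs, 3832 of 9581 cells of library 1 (39.996%, 39.0-41.0) and 4595 of 11598 cells of library 2 (39.6%, 38.7-40.5) held UMIs of at least 3 core cycle genes. No core gene was seen in 19.5% (18.8-20.4) and 21.9% (21.2-22.7) of cells. The class is a range rather than a type: 7.01% and 6.23% of cells had exactly 3 core genes and 14.4% and 13.6% exactly 2. Without thinning the cycling share was 64.3% and 64.4%. Cycling cells held a median of 22701.5 and 20812 UMIs, and non-cycling cells 20097 and 19982.5.

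Cycling cells were set against non-cycling cells to see which functional genes go with division. Outside the core list, and leaving out genes with placeholder names, the largest rises were those of NEK2, a centrosome kinase (log2 fold change 5.99 ± 0.15 SE, n = 2 libraries), CDCA3, a cell division gene (5.99 ± 0.08), and KIF2C, a kinesin that corrects spindle attachments (5.97 ± 0.10). SGO1, which guards sister chromatid cohesion, rose by 5.58, ASPM, a spindle gene, by 5.57, CCNF by 5.38, PIMREG by 5.11 and TTK, a spindle checkpoint kinase, by 5.10. The largest falls under the same rule were those of LCN2, an iron-siderophore binding protein (-2.74 ± 0.07), CEMIP, which breaks down hyaluronan (-2.53 ± 0.06, not passing without clusters 4 to 6 or without the highest doublet scores), and ASPN, a small matrix proteoglycan (-2.51 ± 0.07). CFD, complement factor D (-2.32), PLXNA4, a semaphorin co-receptor (-2.32), OMD, a proteoglycan of bone (-2.21), SULT1A3, a sulfotransferase (-2.09), and PDZK1IP1-2 (-2.03) followed. In all, 1454 of 17048 genes rose and 1675 fell.

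Cycle genes that had not defined the classes rose with them. In the S phase list 37 of 39 genes rose, led by E2F8 (4.92), RAD51AP1 (3.72), EXO1 (3.59) and CLSPN (2.87), which act in replication and repair. In the G2 and M phase list 34 of 40 rose and 6 did not pass: CDC25C, CKAP2, CKAP2L, CKS2, NDC80 and CDCA2 had log2 values between 2.09 and 4.43 but differed between the libraries, as with CKAP2L at 1.05 and 3.89. Since cells were divided on core cycle genes, a rise of other cycle genes is partly built into the classes.

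Of 19 genes of contraction and TGF-beta signalling 13 fell in cycling cells and 0 rose. The largest falls, none of which passed without the replicate block, were those of ACTA2 (smooth muscle actin) at -1.64 ± 0.06, TAGLN (transgelin) at -1.39 ± 0.05, ACTG2 at -1.35 ± 0.12 and THBS1 (thrombospondin 1, an activator of TGF-beta) at -1.10 ± 0.05. Of 18 collagen and matrix genes 9 fell and 0 rose: LOXL2, a collagen cross-linking enzyme, fell by 1.46, ELN (elastin, below 1 CPM) by 1.31, COL12A1 by 0.80 and SPARC by 0.77 on the log2 scale. Matrix remodelling genes went both ways, with MMP3 (2.05, below 1 CPM) and MMP1 (0.70), both matrix metalloproteinases, higher and ADAMTS5 (-0.95) and DCN (-0.74) lower among 16.

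Inflammatory genes fell in 9 of 20 cases and rose in 0. VCAM1, a leukocyte adhesion molecule, changed by -1.83 ± 0.06, and the chemokine genes CXCL14 by -1.44, CCL20 by -1.25 (0.33 and not passing without thinning) and CCL5 by -1.16. Of 21 interferon response genes 5 fell and 0 rose, MX1 by 0.91, USP18 by 0.89, IFI6 by 0.87 and OAS2 by 0.74 on the log2 scale. In the antigen presentation list SLA-DQA1 (-0.77), a class II chain, fell and the other 17 of 18 genes did not pass. Among 22 growth factor genes 9 fell and 2 rose, with IGF1 at -3.30, BDNF at -1.54, GREM1, a BMP antagonist, at -1.19 and IGF2 at -1.05.

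Some genes of mesenchymal lineages also fell. In the adipogenic list 7 of 16 fell and 0 rose, with FABP4 (-1.95, below 1 CPM), APOE (-1.41), ZNF423 (-0.91), a preadipocyte regulator, and CEBPD (-0.81). In the bone and cartilage list 8 of 15 fell and 1 rose: MGP changed by -3.88 and BGLAP by 1.86, both below 1 CPM, and OMD by -2.21 and SOX6, a cartilage transcription factor, by -2.06. Of 14 interstitial progenitor genes 6 fell and 0 rose, with PI16 at -2.50, CD55 at -1.92 (below 1 CPM), LY6E at -1.32 and SEMA3C at -0.99. PI16 was also scarce, at 0.204 CPM in cycling and 1.18 CPM in non-cycling cells, as was LY6E at 0.872 and 2.18 CPM. Of 14 stromal surface genes ITGA1 (-1.22) and ENG (-0.50) fell and CSPG4 (0.55) rose.

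Few genes of hypoxia, cholesterol synthesis, stress and immediate early response changed between cycling and non-cycling cells. Of 20 hypoxia and glycolysis genes ADM (-0.96) and HK2 (-0.56) fell and 0 rose, and of 16 cholesterol synthesis genes FDPS (-0.53) fell and 0 rose. In the stress and unfolded protein list of 17 HSPA8 (0.59), a heat shock chaperone, rose and CHAC1 (-0.74) fell. In the immediate early list of 15 BTG2 (-0.66) and MYC (-0.56) fell and 0 rose. In the senescence and p53 list of 14, 2 rose and 4 fell, with LMNB1 (2.99), which encodes lamin B1, the highest, and GDF15 (-0.92), GADD45A (-0.74) and IGFBP5 (-0.65) lower.

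Calls in the cycling comparison are from edgeR's quasi-likelihood test with BH adjustment, and the counts adjusted over the list alone were equal in all 18 lists. Fry gave a directional adjusted p of at least 0.103 in each list, and a mixed one of 0.0324 for the inflammatory list and at least 0.0697 for the others. Without the replicate block 309 genes rose and 64 fell, and of the genes named here as lower only LCN2, CFD, SULT1A3, PDZK1IP1-2, SPARC, DCN, VCAM1, IFI6 and APOE still passed, and of the rises named outside cycle genes only that of LMNB1.

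**Figure D2:**
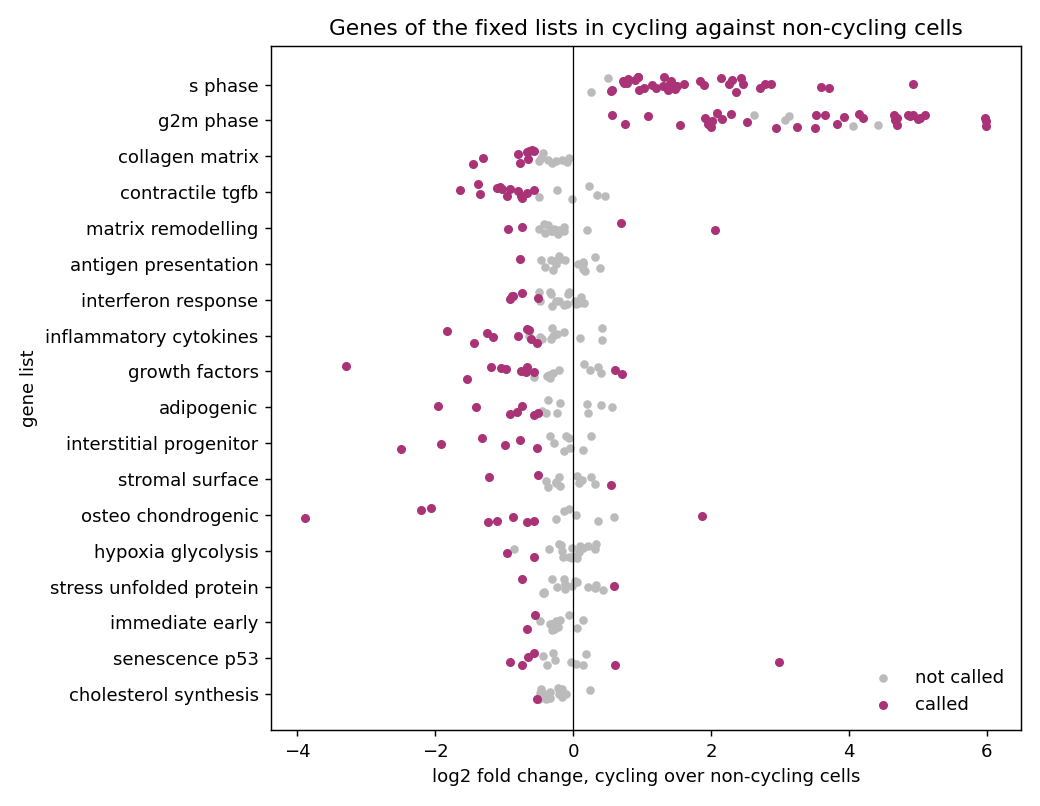
Log2 fold change of each tested gene of the fixed lists in cycling over non-cycling cells, from counts summed over cells in 2 libraries (purple, called; grey, not called). S phase and G2 and M phase genes lie to the right of 0, with 37 of 39 and 34 of 40 called, and 13 of 19 contractile and TGF-beta genes are called to the left.

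Clustering without the list genes gave 6 clusters. Cluster 1 held 46.0% (45.0-47.0) of cells in library 1 and 51.2% (50.3-52.1) in library 2, cluster 2 held 23.8% (22.9-24.6) and 24.2% (23.48-25.02), and cluster 3 held 18.7% (18.0-19.5) and 21.3% (20.56-22.03). Cluster 4 held 5.62% (5.18-6.07) and 1.99% (1.75-2.26), cluster 5 held 4.55% (4.16-4.96) and 1.01% (0.838-1.21), and cluster 6 held 1.38% (1.17-1.62) and 0.234% (0.155-0.338), which left too few cells to test it. ASPN, CEMIP and LCN2 led cluster 1, CDC20, CCNB1 and PTTG1 cluster 2, UBE2C clusters 3 and 6, ACTB cluster 4, and CEMIP with both mitochondrial ribosomal RNAs cluster 5. After thinning 6.11% and 5.74% of cluster 1 cells were cycling, 64.1% and 65.0% of cluster 2 and 92.6% and 91.9% of cluster 3. Cells of cluster 4 held a median of 2158 and 2761 UMIs and of cluster 5 6003.5 and 3524, against 19828 and 19289.5 in cluster 1, so a gap in depth stands beside their shares. The median mitochondrial share was 0.656% and 2.86% in cluster 5.

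**Figure D3:**
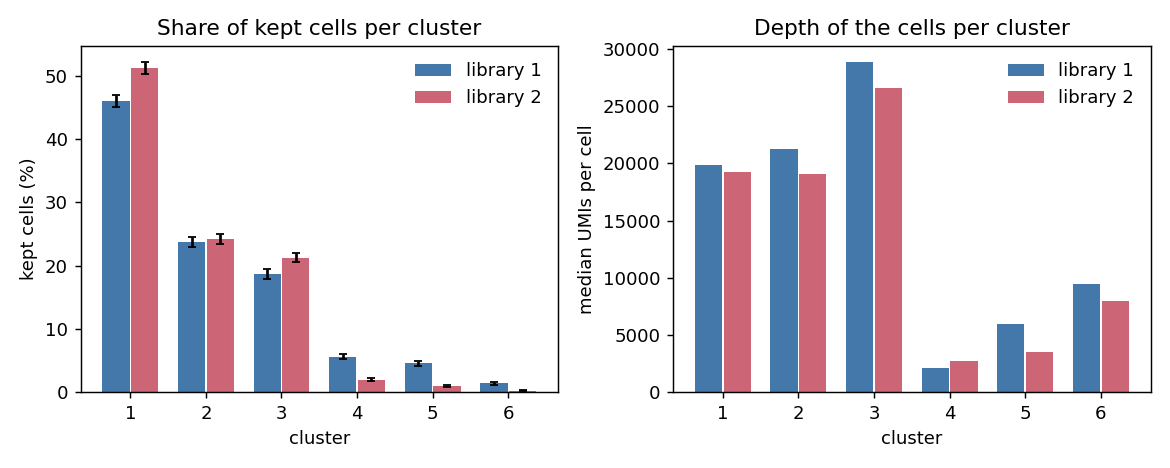
Share of kept cells in each cluster with exact 95% intervals (left) and median UMIs per cell (right) in libraries 1 and 2. Clusters 1 to 3 hold most cells in both libraries, and clusters 4 to 6 hold shallower cells with a larger share in library 1.

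In cluster 1, some genes of contraction, inflammation and cholesterol synthesis were higher than in the mean of the other clusters. OMD rose by 1.55 ± 0.11 (adjusted p = 7.2e-07, edgeR quasi-likelihood, BH, n = 2 libraries), VCAM1 by 1.37 ± 0.08 (1.1e-07) and ACTA2 by 1.15 ± 0.31 (0.0275) on the log2 scale, and MKI67 (-4.61 ± 0.17) and KIF2C (-4.33 ± 0.14) fell most. Of 372 list genes tested 65 were higher and 85 lower (10 and 70 without the replicate block). Of 18 collagen and matrix genes 3 rose and 0 fell, also when adjusted over the list alone, led by SPARC (0.84) and LOXL2 (0.82). Of 19 contractile and TGF-beta genes 9 rose, among them TAGLN (1.12) and MYL9 (0.90), and 10 when adjusted over the list alone. Of 20 inflammatory genes 8 rose (8 adjusted over the list alone), including CXCL14 (1.09) and CCL5 (0.87), and of 16 cholesterol synthesis genes 7 rose (8 adjusted over the list alone), led by MSMO1 (0.82) and FDPS (0.76). Interferon response genes rose in 4 of 21 cases (5 adjusted over the list alone), with IRF9 at 0.85 and MX1 at 0.71. In none of these 4 lists did a gene fall.

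Cluster 2 combined high late-cycle genes with low contractile genes. CCNB1, the mitotic cyclin B1, rose by 2.29 ± 0.11, CDC20, which activates the anaphase-promoting complex, by 2.13 ± 0.16, and DLGAP5, a spindle gene, by 2.01 ± 0.10, while ACTA2 (-2.0 ± 0.38) and SOX6 (-1.72 ± 0.23) fell most. The 3 rises are against a mean of log values that takes in clusters low in cycle genes. Averaged as CPM, CCNB1 was at 150.3 against 73.28 in the other clusters, CDC20 at 321.9 against 142.2 and DLGAP5 at 134.9 against 72.19. In all, 59 list genes rose and 47 fell (32 and 10 without the replicate block). Of 40 G2 and M phase genes 22 rose and 1 fell (23 and 1 adjusted over the list alone), and of 19 contractile and TGF-beta genes 8 fell and 1 rose (8 and 2 adjusted over the list alone), with TAGLN at -1.40, THBS1 at -1.36 and TPM1 at -1.08. Of 15 bone and cartilage genes 6 fell and 0 rose, also when adjusted over the list alone, with SOX5 at -1.17 and OMD at -1.12. The core cycle gene TOP2A, a topoisomerase, fell by 1.59 on the log2 scale.

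Cluster 3 had the highest cycle genes. TOP2A rose by 4.31 ± 0.12, UBE2C, a ubiquitin-conjugating enzyme of mitosis, by 4.26 ± 0.15 and CDK1, the mitotic kinase, by 4.15 ± 0.09, and SOX6 (-1.45 ± 0.21) and OMD (-1.19 ± 0.14) fell most. In all, 102 list genes rose and 44 fell (84 and 5 without the replicate block). Of 39 S phase genes 38 rose (38 adjusted over the list alone), led by E2F8 (3.18) and RAD51AP1 (2.62), and 0 fell. Of 18 collagen and matrix genes 5 fell and 0 rose, also when adjusted over the list alone, including FBN1 (fibrillin 1, -0.89), COL12A1 (-0.88) and COL5A2 (-0.85). Of 22 growth factor genes 6 fell and 0 rose (6 and 1 adjusted over the list alone), with ANGPT1 at -0.96 and PDGFC at -0.77.

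The shallow clusters 4 and 5 differed from each other. In cluster 4, 39 list genes rose and 9 fell (27 and 0 without the replicate block): TOP2A rose by 2.07 ± 0.17, UBE2C by 1.90 ± 0.17 and AURKB, a mitotic kinase, by 1.80 ± 0.21, and ZNF423 (-1.35 ± 0.32) and COL5A1 (-0.97 ± 0.20) fell most. These rises are against a mean of log values that takes in clusters 1 and 5, where cycle genes are low: averaged as CPM, TOP2A was at 111.5 against 103.2 in the other clusters, UBE2C at 208.8 against 215.3 and AURKB at 38.81 against 40.59. In cluster 5 the median log2 fold change of all genes was 0.38, and values for it are given relative to that median. SOX6 was higher by 2.68 ± 0.19, ZNF423 by 2.17 ± 0.14 and SOX5 by 1.64 ± 0.15, and NUF2, a kinetochore gene (-3.67 ± 0.26), and PLK1, a mitotic kinase (-3.51 ± 0.24), were lowest. In cluster 5, tested against 0, 68 list genes were called higher (34 without the replicate block) and 125 lower (85); of the 68, 51 stayed past the minimum fold relative to the median. Relative to it, 12 of 20 hypoxia and glycolysis genes were lower and 2 higher, with LDHA at -2.67, TPI1 at -2.37 and PGAM1 at -2.30, and 11 of 18 antigen presentation genes were lower and 1 higher, with PSMB9 at -2.93 and B2M at -1.65. Collagen and matrix genes were higher in 7 of 18 cases and lower in 2, with LOXL2 at 1.46, COL5A1 at 1.43 and FBN1 at 1.38. Counted genes also had to be called against 0, which relative to the median is stricter for lower genes than for higher ones. COL1A2 (-0.74), BGN (-0.61) and COL3A1 (-0.59) were not counted as lower, and COL1A1 was at -0.05. Across all genes compared, the change in cluster 5 against clusters 1 to 3 rose with gene span (Spearman 0.68 and 0.78 in libraries 1 and 2), so these list changes are not separate from it.

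Clusters were formed on other genes of the same cells, and PTTG1, a cycle gene outside the lists, was among those leading cluster 2. Calls of cycle list genes across clusters are therefore partly built in. In all, 275 of the 372 list genes were called in at least 1 cluster. Without the replicate block 163 were, with the calls of ACTA2 in clusters 1 and 2, OMD in cluster 3 and ZNF423 and COL5A1 in cluster 4 lost, and the number of clusters moved between 5 and 12 with the resolution and to 8 when 1 and 5 cells above 10% mitochondrial UMIs were left out, so the borders of clusters depend on the settings.

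**Figure D4:**
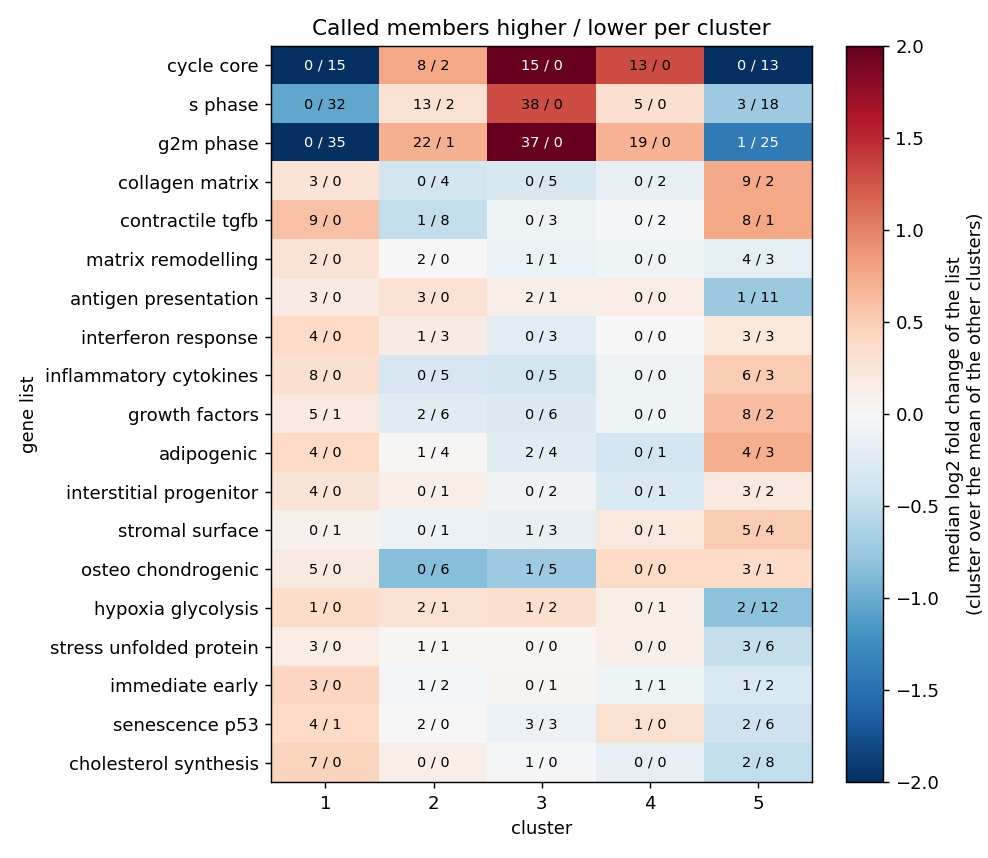
Median log2 fold change of each gene list in each tested cluster against the mean of the other clusters (colour, limited at -2 and 2), with the numbers of called members higher and lower. Cell cycle lists are lowest in cluster 1 and highest in cluster 3, and cluster 5 values include the median of all genes there, 0.38.

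CD74, the invariant chain of MHC class II and a surface marker that has been used to sort a subset of ADSCs, was barely detected. Library 1 held 157 and library 2 held 177 CD74 UMIs (0.749 and 0.721 CPM). After thinning, 29 of 9581 cells (0.303%, 0.203-0.434) and 46 of 11598 cells (0.397%, 0.291-0.529) had a CD74 UMI, and 0 had more than 1 (counting limits 0.0313% and 0.0259%), which at so few UMIs says nothing of the share of cells expressing CD74. Without thinning 156 (1.48%, 1.26-1.73) and 175 cells (1.46%, 1.25-1.69) had one. After thinning, most endothelial and lymphocyte markers were seen in smaller shares than CD74, such as CDH5 in 0.0209% and 0.00862% and CD79B in 0.0104% and 0.0172%, and a few in larger ones, such as EMCN in 3.06% and 2.97% and CD247 in 3.58% and 3.73%. The class II genes SLA-DRA (1 and 0 UMIs), SLA-DRB1 (2 and 4), SLA-DMA (9 and 6) and SLA-DOA (5 and 0) were close to 0. SLA-DQA1 (459 and 420), SLA-DMB (328 and 452) and SLA-DQB1 (196 and 245) held more UMIs than CD74. CIITA, the regulator of class II genes, had 67 and 94 UMIs.

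CD74-detected cells were too few for the comparison with CD74-zero cells as designed, being under 50 in each library. With no thinning it could be run, and 13 of 17706 genes rose and 3 fell in edgeR's quasi-likelihood test with BH adjustment, with 1154 genes at an unadjusted p under 0.05. TOX rose by 0.80 on the log2 scale (0.13 in library 1 and 1.12 in library 2). MCM8, a helicase of DNA repair, rose by 0.74 (1.15 and 0.27), and ALDH1A1, a retinaldehyde dehydrogenase, fell by 0.54 (-0.46 and -0.61). None of the genes in the 19 lists was called, and the smallest fry adjusted p was 0.306. Without the replicate block 0 genes were called, and 0 with DESeq2. CD74-detected cells were deeper. In all, 156 and 175 cells held a UMI, against 153-157 and 173-177 when the UMIs were placed at random by depth. At so few UMIs this cannot tell a chance spread from expression in a part of the cells.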

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

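The signal below lies in barcodes left out of all comparisons, and no test was run on it. Barcodes above the mitochondrial limit of 15% numbered 17 in library 1 and 100 in library 2, and the median share of mitochondrial ribosomal and transfer RNA in them was 19.05% and 27.82%. In kept cells it was 0.137% and 0.112%. These barcodes made up 0.139% (0.0809-0.222) and 0.772% (0.628-0.938) of all barcodes, with medians of 716 and 676 UMIs. All of them also fell under the minimum number of genes.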

How the results depend on the processing

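Settings without the highest doublet scores and without clusters 4 to 6 were chosen after seeing the data. Across settings 117 of 153 counts and shares kept within 1.5 times or their interval and 36 moved; of 162 list medians 149 kept their direction and side of the threshold, 9 passed it newly and 4 changed sign; of 1192 values of named genes 1081 kept both, 110 no longer passed and 1 changed sign. Without the replicate block 309 genes rose and 64 fell in cycling cells, and 163 list genes were called in any cluster: 10 higher in cluster 1, 32 higher and 10 lower in cluster 2, 5 lower in cluster 3, 0 lower in cluster 4 and 34 higher in cluster 5. All 163 and all 64 were also called with the block, as were 307 of the 309. With no minimum fold change 3796 rose and 3963 fell in cycling cells, and with a minimum of 1 705 rose and 570 fell, by construction. That minimum left 182 list genes in any cluster: 17 higher in cluster 1, 25 higher and 18 lower in cluster 2, 8 lower in cluster 3, 22 higher and 2 lower in cluster 4 and 41 higher in cluster 5. DESeq2 called 1005 genes lower in cycling cells, 977 of them shared. Without clusters 4 to 6, 35 list genes rose in cluster 2, where the reference is smaller. The cycling share was 25.79% and 25.93% with 2000 UMIs, 64.26% and 64.35% without thinning, 27.44% and 28.09% with at least 5 core genes, and in library 2 38.7% without the highest doublet scores. The CD74 share was 0.194% and 0.168% with 2000 UMIs, 1.48% and 1.46% without thinning and 0% in both with at least 2 UMIs. With fewer UMIs kept per cell fewer genes are seen, which by construction lowers the share at 2000 UMIs and raises it without thinning, and the stricter rules lower it on the same cells. Without thinning 1248 genes rose and 1184 fell in cycling cells, but only 831 and 753 of them were shared with the 1454 and 1675. There the cycling difference changed sign for CCL20 (0.33) and for the list medians of antigen presentation (0.25), stromal surface (0.0071) and hypoxia and glycolysis (0.21), the last also without the highest doublet scores (0.0050); the cause was not tested. CEMIP also lost its call without clusters 4 to 6 and without the highest doublet scores. With either library left out, values with no test gave 1302 to 1378 genes higher and 1447 to 1550 lower in cycling cells, and 260 to 268 list genes in any cluster. The clustering gave 5, 12, 8, 7 and 8 clusters at resolution 0.2, at 0.8, with joint scaling, with list genes kept and with 10% mitochondrial UMIs. That limit removed 1 and 5 kept cells, so the number of clusters moves with few cells, and no thinned cell, so it tests nothing for the cycling and CD74 classes. Removal of called doublets was void, since none were removed. Other planned settings of the CD74 comparison were not run, since its classes were too small. The CD74 result rests on 157 and 177 UMIs in all.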

Other observations

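Chosen only after the result was seen were the values in the next paragraph and the tests of gene span in clusters 5 and 4, of the ratio of UMIs between clusters 2 and 3, of cluster 3 cells of low depth, and of doublets or free RNA; the other tests of the 3 patterns were set before their results.

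Among non-cycling cells of clusters 1 to 3 (1783 in library 1 and 2514 in library 2), ACTA2 varied most from cell to cell by the Fano factor (variance over mean of the thinned UMIs), ranked on the lower value of the libraries. It was 11.7 and 15.5, against a median of 1.05 and 1.04 over 5267 genes. S100A4, a calcium-binding protein (12.3 and 11.4), SFRP2, a Wnt modulator (6.93 and 8.47), TAGLN (6.18 and 7.66), CEMIP (5.39 and 15.01) and the chemokine gene CCL2 (5.30 and 6.17) also had high values. The abundant S100A6 (10.6 and 11.2) and VIM (12.8 and 9.67) did too. The Fano factor was not adjusted for abundance. S100A4 had a mean of 37.7 and 35.1 thinned UMIs per cell against 0.598 and 0.919 for ACTA2, so their values are not directly comparable. Cells are not replicates, so no p-value is given.

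Immediate early genes were higher in library 1 than in library 2 by a median log2 of 0.73. A larger share of shallow cells in library 1 (clusters 4 to 6) is argued against, since inside cluster 1 alone the median was 0.80. The ratio between libraries fell with gene span (Spearman -0.42 across genes), but after removal of that trend the list median was still 0.64, above all 10000 random lists. A difference in how the cells were handled, cultured or dissociated may remain, and the labels give no batch that would test it. The design names no biological difference between the libraries, so no biological explanation was tested.

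In cluster 5 68 list genes were higher (51 past the minimum fold relative to the median of all genes), with SOX6, ZNF423 and SOX5 the largest among those of at least 10 CPM. Against cluster 1, also low in cycling cells, those genes were higher by a median log2 of 1.16 and 1.70 in libraries 1 and 2. Relative to the median of all genes the values were 0.92 and 1.21. The genes were chosen as higher against a mean that takes in cluster 1, so part of this rise is built in. Of thinned cells 14.4% of 277 and 12.8% of 39 were cycling in cluster 5, against 6.11% and 5.74% in cluster 1. The core cycle list was higher in cluster 5 than in cluster 1 by a median log2 of 1.003 and 1.045. Fewer cycling cells would not raise genes over cluster 1, so these values argue against them as the whole cause for these genes. Cells that lost cytoplasmic RNA and kept nuclear RNA, rich in long unspliced transcripts, may account for the higher list genes: against clusters 1 to 3 the change in cluster 5 rose with gene span (Spearman across genes 0.68 and 0.78), with medians of -0.51 and -1.31 in the 25% of genes with the shortest span and 1.38 and 1.90 in the 25% with the longest. Low UMI counts alone cannot be told apart from this, since in the still shallower cluster 4 the correlation was 0.42 in library 1 and 0.20 in library 2 against clusters 1 to 3, but -0.10 and -0.53 when cluster 5 was part of the reference, as first computed; the reference was changed after those values were seen because cluster 5 pulls cluster 4 down. No biological explanation was tested.

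In cluster 2 CCNB1 (145 and 137 CPM) and CDC20 (315 and 288 CPM), with PTTG1 and DLGAP5, were near their level in cluster 3 (189 and 166, 355 and 286 CPM), while TOP2A was at 11.3 and 15.7 CPM against 304 and 387 and CDK1 at 8.44 and 7.05 against 143 and 104 CPM; the wording of this pattern was corrected after its values were seen. For depth, cluster 2 was set against the 650 and 932 cluster 3 cells with no more UMIs than its median cell. Against these the log2 ratio of the first 4 genes to TOP2A and CDK1 was still higher in cluster 2 by 3.95 and 3.96. Against all cluster 3 cells it was higher by 3.99 and 3.98. The shallower cells were placed in cluster 3 by their expression, and such a ratio of summed counts hardly depends on depth. The comparison therefore cannot exclude fewer UMIs per cell. It replaced a test by thinning, which leaves such a ratio unchanged whatever the cause. Doublets with cluster 3 cells, or their free RNA, would bring in all cluster 3 genes at about the same share if those cells contribute evenly. Such an even share is argued against as the whole cause by 43 of 132 other genes at least 4-fold higher in cluster 3 than in cluster 1. In both libraries their excess was under 50% of the smallest of the first 4 genes (69.8% and 74.8% of the excess in cluster 3), beyond Poisson error. CENPF, for example, was at 65.5 and 81.2 against 475 and 606 CPM. The first 4 genes were among those leading cluster 2, so a lower excess of other genes is partly built in. Doublets with only part of the cluster 3 cells need not bring an even share and were not tested. The count of 43 was chosen after the median of the 132 (37.2% and 36.95%) had missed in library 1 a bound at 50% of the smallest. Both replaced a comparison with TOP2A and CDK1, which define the pattern. Cells that divided shortly before, with CCNB1 and CDC20 transcripts left over, may be a candidate explanation. The median UMI count in cluster 2 was 0.736 and 0.717 of that in cluster 3, but 1.07 and 0.988 of that in cluster 1. Of thinned cluster 1 cells 6.11% and 5.74% were cycling and 34.7% and 38.4% non-cycling. The late-cycle genes PLK1 (59.8 and 61.0 against 154 and 148 CPM) and AURKA (26.9 and 23.9 against 91.4 and 82.3 CPM) were also well below cluster 3. The design gives no group that bears on recent division, so no biological explanation from the design was tested.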
